A study of Mus musculus with 3 samples.

How the data were processed

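The data are peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse neural stem cells. Per the labels, the cells came from the cerebral cortex of wild-type embryos at embryonic day 12.5, were grown with EGF and FGF, and were treated with TGFb at 5 ng/ml. The series text gives 30 minutes of TGFb for the Smad3 and JMJD3 immunoprecipitations. The labels name 3 libraries, 1 of Smad3, 1 of JMJD3 and 1 of input DNA with no antibody. Peak lists of the Smad3 and JMJD3 libraries were used. A list of the input library was not used here.

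Per the submitters' processing notes, the tools named are CASAVA, Bowtie 0.12.7 and MACS 1.4, and the genome build is mm9. Which step each tool carried out, the thresholds, and how the input library entered peak calling are not given in the sources used here. The deposited files hold 1 row per peak with its chromosome, start and end, the signed distance from the closest RefSeq transcription start site (TSS) to the peak's midpoint, and the transcript, symbol and Entrez ID of that gene. They carry no height, fold enrichment, p-value or read number, so the depth behind each peak is unknown. Peaks were listed per library. All coordinates are those of the files, on mm9.

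The tests had been planned on a peak score. With none in the files, the strength of a peak was replaced by the width of its region, defined by joining peaks of the same list that lay at most 10 bp apart. This departs from the planned measure, and width is an imperfect stand-in for enrichment. A gene counted as bound when a peak that named it as the closest gene had its midpoint within 1 kb of that TSS, and its region width was that of the widest such region. Since each peak names only its closest TSS, a divergent promoter can credit 1 gene of the pair.

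The number of peaks sharing at least 1 bp with the other list was compared with 1000 random placements of the same peaks within their chromosome, between the first and last peak of either list (one-sided permutation p, smallest possible value 0.001). Values per distance class used 100 placements. Overlap near and far from TSS was compared by two-sided Fisher exact tests. Region widths of overlapping and other peaks were compared by a two-sided permutation test of the difference in median rank percentile (100000 permutations, smallest possible p 1e-05). Gene-level binding was tested by two-sided Fisher exact tests over 20953 protein-coding genes with a curated mRNA on chromosomes 1 to 19 and X. That background came from a RefSeq gene table of assembly GRCm38.p6, later than the build of the files, and was used for names and for the set of background genes, matched on Entrez ID, and not for coordinates. Of 16428 genes named in the files, 16331 (99.4%) matched.

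Before the data were examined, 15 gene lists were fixed, covering TGF-beta signalling, stem cell, neuronal, glial, pathway, chromatin, housekeeping and other-lineage genes. Each was tested for Smad3, JMJD3 and both, with Benjamini-Hochberg adjustment over the 45 tests. Whether a list differed between the factors was tested on genes bound by only 1 of them (exact McNemar test within the list, and two-sided Fisher exact test against all other such genes, adjusted over 15 lists). The rule for named genes was fixed at the same time, with a peak score where width is now used. It took the 10 widest regions at promoters for each factor and the 10 genes with the highest lower width percentile of the Smad3 and JMJD3 regions, skipping predicted genes, unnamed genes and microRNAs. From each list it took up to 4 members bound by both, ranked by the same lower percentile, and 2 bound by 1 factor with the widest regions, and it always included Smad3, Kdm6b, Smad2, Smad4, Smad7, Ctgf, Dbx1, Neurog2 and Sox2. Some genes that the rule takes are not reported here. Genes named outside the rule were chosen after their values were seen.

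Further tests were chosen after the data were seen, as was the sorting of regions into classes of width. JMJD3 binding was compared between the Smad3-bound members of a list and other Smad3-bound genes (two-sided Fisher exact test, adjusted over 15 lists), and with random Smad3-bound genes of like region width. Region widths and numbers of distal regions of a list were compared with 10000 random lists of the same size (two-sided permutation test on medians, smallest possible unadjusted p 0.0002).

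Alternatives covered midpoints within 200 bp, reciprocal overlap of 50%, the wider 50% of peaks, the widest 1000 peaks, circular shifts, placement at matched distances from random TSS, TSS windows of 2.5 and 5 kb, equal numbers of peaks, and other gene backgrounds. The random TSS came from those named as closest to a peak in either list. A planned search for sequence elements in the peaks was not run, because no sequence of the files' build was used here. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. With 1 library per antibody and no untreated library, no test compared conditions, and every p-value describes these peak lists, not replicate cultures. The overlap and gene list tests were tested on simulated data. A simulated list of 63154 peaks placed independently of Smad3 overlapped it 0.981 times as often as random placements. For lists of 40 genes among the 20953, 5% of random lists had p at most 0.05, as did 98% of lists drawn with the odds of JMJD3 binding raised 4-fold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.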

Results

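Smad3 is the transcription factor that carries TGF-beta receptor signals to chromatin, and JMJD3, the product of Kdm6b, is a demethylase of histone H3 lysine 27. The series asked where both proteins sit on the genome of cortical neural stem cells treated with TGFb. The Smad3 list held 98086 peaks covering 38.4 Mb, with a median width of 351 bp. The JMJD3 list held 63154 peaks covering 32.4 Mb, with a median width of 490 bp. Joining peaks at most 10 bp apart left 70562 Smad3 and 45018 JMJD3 regions. There was 1 library per antibody, so no value has a replicate error, and no untreated library, so no value shows an effect of TGFb.

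Smad3 and JMJD3 had similar shares of peaks at promoters and differed more at other distances. Of the Smad3 peaks, 25.4% (95% CI 25.1 to 25.7) lay within 1 kb of a TSS and 28.6% lay more than 50 kb from any. The JMJD3 shares were 25.2% (24.8 to 25.5) and 31.8%. Between 1 and 5 kb lay 11.1% (10.9 to 11.3) of Smad3 and 8.70% (8.48 to 8.93) of JMJD3 peaks. Over the 15353 coding TSS closest to a peak, coverage was highest just upstream of the start, where Smad3 peaks covered 67.5% of TSS at -50 bp and JMJD3 peaks 55.5% at -100 bp. At 1 kb downstream, coverage had fallen to 11.3% for Smad3 and 6.21% for JMJD3. Inside the closest gene but beyond 1 kb of its TSS lay 27.3% of Smad3 and 26.6% of JMJD3 peaks. In the 50% of peaks with the wider regions, the promoter share was larger, at 36.6% for Smad3 and 35.4% for JMJD3.

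**Figure D1:**
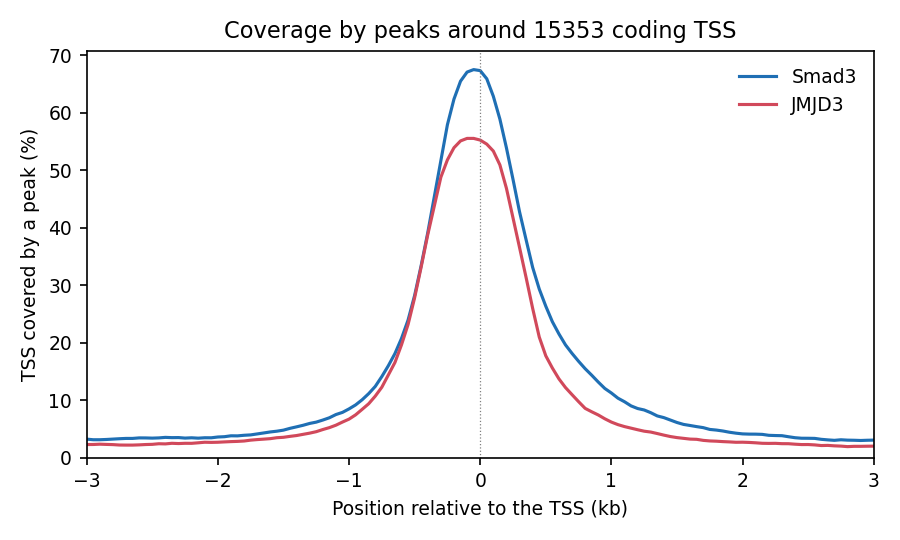
Percent of 15353 coding TSS (vertical axis) covered by a Smad3 peak (blue) or a JMJD3 peak (red) at each position from 3 kb upstream to 3 kb downstream of the TSS (horizontal axis, kb). Both curves peak within 100 bp upstream of the TSS, at 67.5% for Smad3 and 55.5% for JMJD3.

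Most JMJD3 peaks lay on Smad3 peaks. Of 63154 JMJD3 peaks, 51386 (81.4%) overlapped a Smad3 peak, and of 98086 Smad3 peaks, 59062 (60.2%) overlapped a JMJD3 peak. Random placement gave 2.92% and 2.04%, so overlap was 27.8-fold and 29.6-fold above it (one-sided permutation p = 0.001 for each, the smallest the 1000 placements allow). The Smad7 promoter on chromosome 18 is an example, with a Smad3 region at 75525881 to 75528090 and a JMJD3 region at 75525881 to 75528160. Placement that kept each peak's distance from a TSS raised the random shares to 19.8% and 14.7%, and the observed overlap was 4.10-fold above it in each direction (one-sided permutation p = 0.001). Among the widest 1000 peaks of each list the shares were lower, 31.4% and 37.8%, where random placement of these shorter lists gave 0.0282% and 0.0356%.

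Overlap was highest at promoters but was not confined to them. Within 1 kb of a TSS, 93.4% (95% CI 93.0 to 93.8) of JMJD3 peaks overlapped Smad3, against 77.3% of the rest (odds ratio 4.13, 95% CI 3.87 to 4.42). For Smad3 peaks the shares were 70.9% (70.3 to 71.5) and 56.6% (odds ratio 1.87, 1.81 to 1.93). Both two-sided Fisher exact p-values were too small for double precision. Beyond 50 kb of any TSS, 75.2% of JMJD3 peaks and 60.8% of Smad3 peaks still overlapped the other factor, where TSS-matched placement gave 5.28% and 3.58%. Within 1 kb, TSS-matched placement gave 61.2% and 46.3%, so overlap exceeded it by less at promoters than far from them. The random TSS were drawn from those named as closest to a peak in these lists. That choice raises the random share at promoters, so part of the smaller excess there was built in.

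**Figure D2:**
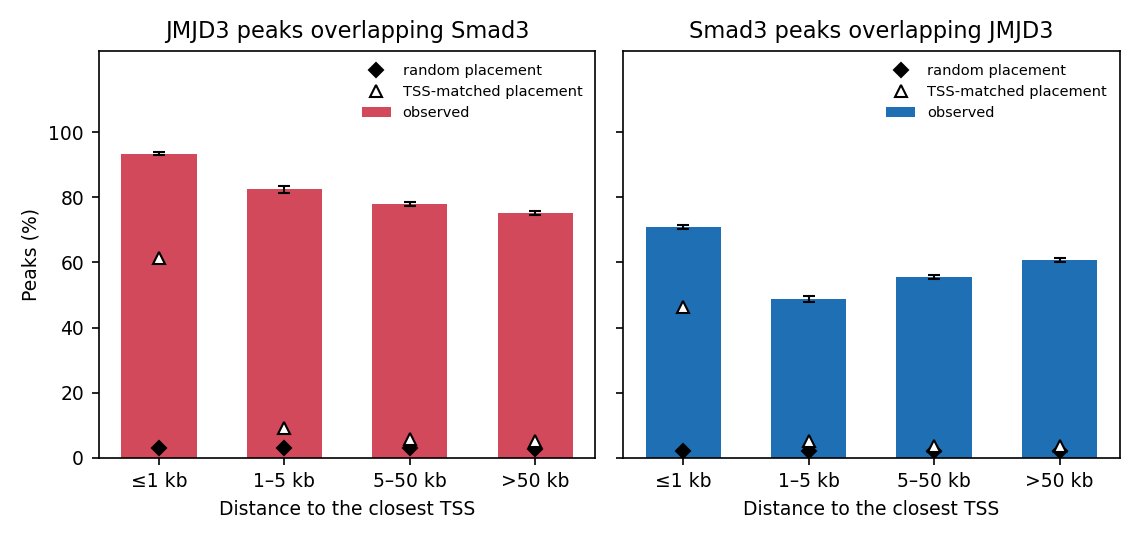
Percent of JMJD3 peaks overlapping Smad3 (left, red bars) and of Smad3 peaks overlapping JMJD3 (right, blue bars) by distance to the closest TSS, with 95% Clopper-Pearson intervals, diamonds for random placement within the chromosome and triangles for placement at matched distances from random TSS. Bars range from 75.2% to 93.4% for JMJD3 and from 48.8% to 70.9% for Smad3, above both kinds of random placement in every class.

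Peaks shared by both factors lay in wider regions. Shared JMJD3 peaks had a median region width of 800 bp against 490 bp for unshared ones, and Smad3 peaks 720 bp against 390 bp. In rank percentiles of width the medians differed by 36.5 points for JMJD3 and 35.3 points for Smad3 (two-sided permutation p = 1e-05 each, the smallest 100000 permutations allow). Random placements of single peaks gave mean differences of 25.4 bp and 31.4 bp. When Smad3 regions were sorted into 10 classes of equal size, a split chosen after the data were seen, the share overlapping JMJD3 went from 27.3% in the narrowest to 93.6% in the widest class. For JMJD3 regions it went from 49.9% to 99.5%.

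**Figure D3:**
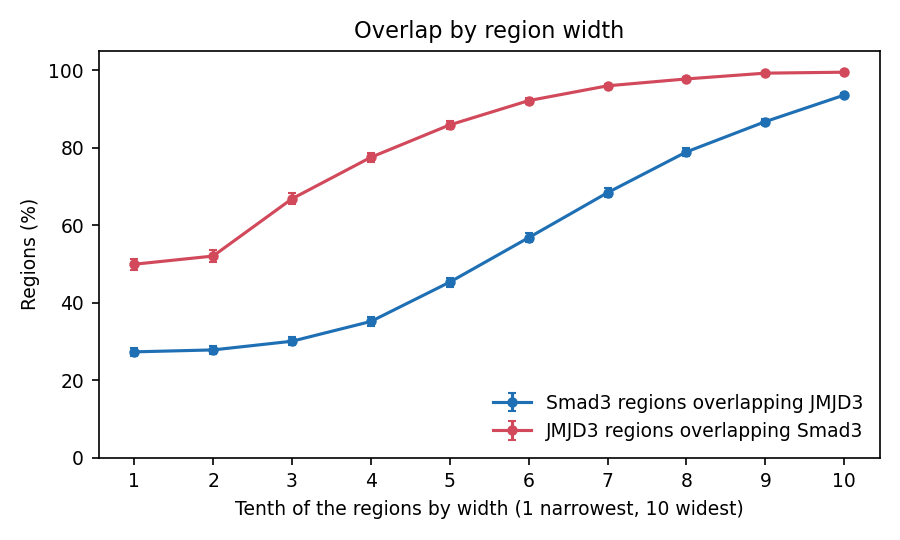
Percent of Smad3 regions overlapping JMJD3 (blue) and of JMJD3 regions overlapping Smad3 (red), for regions sorted by width into 10 classes (horizontal axis, 1 narrowest), with 95% Clopper-Pearson intervals. The share goes from 27.3% to 93.6% for Smad3 and from 49.9% to 99.5% for JMJD3.

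At gene promoters, nearly every JMJD3-bound gene also had a Smad3 peak. Smad3 peaks lay within 1 kb of the TSS of 11524 of 20953 coding genes (55.0%) and JMJD3 peaks of 9077 (43.3%). Both factors were listed at 8780 genes, where independent binding would give 4992 (odds ratio 98.4, 95% CI 87.0 to 111; two-sided Fisher exact p too small for double precision). JMJD3 without Smad3 was found at 297 genes and Smad3 without JMJD3 at 2744. Of the 297, 129 had a JMJD3 promoter peak that did overlap a Smad3 peak, 1 that was listed under another gene or centred farther than 1 kb from the TSS.

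Among named coding and long non-coding genes, the widest Smad3 promoter regions included TGF-beta response genes and a progenitor marker. The widest lay at Id1 (Entrez 15901), which encodes an inhibitor of basic helix-loop-helix factors, with 5680 bp on chromosome 2 from 152560251 to 152565930. It was followed by Nes (Entrez 18008), the intermediate filament nestin of neural progenitors, with 4910 bp, and Klf10 (Entrez 21847), a TGF-beta early response gene, with 4621 bp. Nab2, Neat1, Id3, Cxxc5, Dusp6, Fam173a and Crip2 followed, at 4480, 4391, 4111, 4051, 3991, 3931 and 3640 bp. All 10 also had a JMJD3 promoter region, from 780 bp at Cxxc5 to 3480 bp at Klf10.

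The widest JMJD3 promoter regions lay at Klhl21 (3500 bp), Klf10 (3480 bp) and Brd2 (3311 bp), a bromodomain protein gene. Cdc42se1 and its neighbour Mllt11 shared a region of 3300 bp on chromosome 3. Jund, an AP-1 subunit, had 3290 bp, Crlf2 3270 bp, Fam173a 3250 bp, Hes1, a Notch effector, 3211 bp, and Kifc3 3171 bp. Each had a Smad3 promoter region too, from 1281 bp at Jund and Kifc3 to 4621 bp at Klf10. Among genes wide for both factors were also Cnn3, Npas3 and the histone genes Hist2h2aa1, Hist2h2aa2 and Hist2h3c1, which share 1 region of 3070 bp for Smad3 and 2990 bp for JMJD3.

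Genes of the TGF-beta pathway were bound by both factors more often than other genes. Smad3 was listed at 39 of 43 members (90.7%, 95% CI 77.9 to 97.4) and JMJD3 at 31 (72.1%, 56.3 to 84.7), against 54.9% and 43.3% of other genes. The adjusted p-values (two-sided Fisher exact test) were 1.94e-06 for Smad3, 0.000318 for JMJD3 and 0.000153 for the 31 genes with both. Klf10, Id1, Skil and Smad7, the last 2 encoding feedback inhibitors of the pathway, ranked highest in the list by the lower of their Smad3 and JMJD3 width percentiles. At Skil the Smad3 region was 3151 bp and the JMJD3 region 2521 bp, and at Smad7 2210 bp and 2280 bp. Smad7 was the closest gene of 49 Smad3 and 38 JMJD3 peaks. Zeb1 and the co-receptor gene Tgfbr3 had Smad3 regions of 1311 bp and 970 bp and no JMJD3 promoter peak. Against only those genes that are closest to any peak, Smad3 kept its call (odds ratio 4.33, adjusted Fisher exact p = 0.0159) and JMJD3 and both did not (odds ratios 1.95 and 2.11, adjusted p = 0.0951 and 0.055).

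The genes of the studied proteins and their partners were mostly bound. Smad3 itself had a Smad3 region of 1770 bp (chromosome 9, 63605121 to 63606890) and a JMJD3 region of 2180 bp. Smad2 had 1430 bp and 1580 bp, Smad4 1350 bp and 840 bp, and Ctgf, a classic TGF-beta target, 981 bp and 1120 bp. Kdm6b, which encodes JMJD3, had a Smad3 region of 440 bp, and its nearest JMJD3 peak lay 1531 bp downstream of the TSS. The proneural gene Neurog2 had a Smad3 region of 331 bp and a JMJD3 region of 460 bp. Dbx1, a patterning factor of the neural tube, had no promoter peak listed, and its nearest Smad3 and JMJD3 peaks lay 26064 bp and 49934 bp away.

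**Figure D4:**
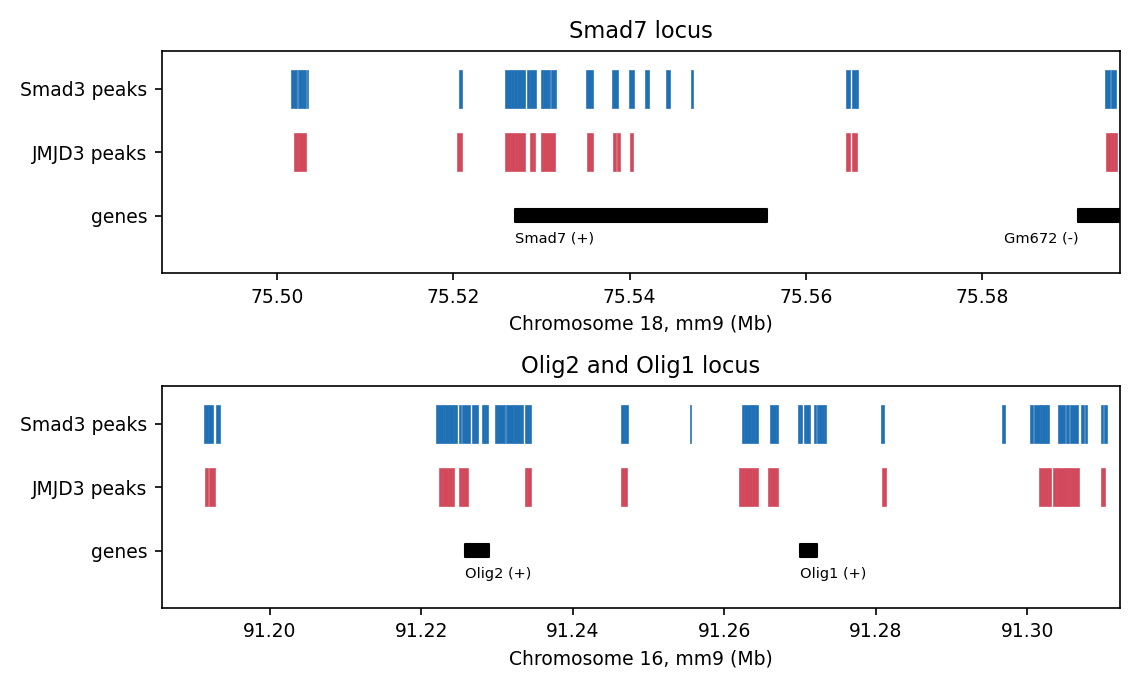
Smad3 peaks (blue), JMJD3 peaks (red) and genes (black, with strand) around Smad7 on chromosome 18 and around Olig2 and Olig1 on chromosome 16 (horizontal axes, mm9 position in Mb). Peaks of both factors cover the Smad7 and Olig2 promoters, while the Olig1 promoter has Smad3 peaks and its nearest JMJD3 peak is centred 3461 bp upstream.

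Neural stem and progenitor genes were among the lists most widely bound. Smad3 was listed at 34 of 36 members (94.4%, adjusted Fisher exact p = 9.23e-07) and JMJD3 at 31 (86.1%, adjusted p = 7.67e-07), and all 31 had both. Hes1, Notch1, Hes6 and Rfx4 ranked highest by the lower of the same percentiles, with Smad3 regions of 2780, 2441, 2180 and 2560 bp and JMJD3 regions of 3211, 3090, 2030 and 1880 bp. Sox2, a core factor of neural stem cells, had a Smad3 region of 2351 bp and a JMJD3 region of 970 bp. Sox3 and Msi1 had Smad3 regions of 590 bp and 471 bp and no JMJD3 promoter peak. These calls held against genes closest to any peak (adjusted Fisher exact p = 0.0159, 0.00327 and 0.00118 for Smad3, JMJD3 and both).

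Genes of the Notch pathway were also bound more often, with Smad3 at 24 of 30 (80.0%, adjusted Fisher exact p = 0.00754) and JMJD3 at 23 (76.7%, adjusted p = 0.000531). The ligand genes Jag1 and Dll1 had Smad3 regions of 2070 bp and 1890 bp and JMJD3 regions of 1640 bp and 1060 bp. Dll3 and Maml2 had Smad3 promoter peaks only. In the Wnt list Smad3 was found at 28 of 35 genes (80.0%, adjusted Fisher exact p = 0.00459) and JMJD3 at 25 (71.4%, adjusted p = 0.0016), among them Gsk3b, Axin1, Axin2 and Fzd9. The Wnt members Fzd10 and Wnt4 had Smad3 promoter peaks only, although the nearest JMJD3 peak of Wnt4 was centred 1003 bp from its TSS, just past the 1 kb limit. Neither list passed against genes closest to any peak (adjusted p from 0.0643 to 0.466 for Notch and from 0.167 to 0.47 for Wnt). BMP pathway genes did not differ detectably from other genes, with Smad3 at 14 of 21 and JMJD3 at 12 (adjusted Fisher exact p = 0.44 and 0.348). Acvr2a, Acvr1, Bmpr2 and Smad5 were bound by both, and Smad9 and Gdf11 by Smad3 only.

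Neurogenic and patterning transcription factors were not bound more often than other genes. Smad3 was listed at 27 of 50 (54.0%, 95% CI 39.3 to 68.2) and JMJD3 at 18 (36.0%, 22.9 to 50.8), with adjusted Fisher exact p = 0.888 and 0.389. Olig2, Sox4, Insm1 and Sox11 were bound by both, with Smad3 regions of 1440, 1160, 1120 and 2080 bp and JMJD3 regions of 1150, 1000, 980 and 930 bp. Dlx2 and Olig1 had Smad3 regions of 981 bp and 830 bp and no JMJD3 promoter peak. Against genes closest to any peak, these factors were bound less often by JMJD3 (adjusted Fisher exact p = 0.0394) and by both (adjusted p = 0.031).

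Genes of differentiated neurons and glia gave no call either with the 1 kb window. Among neuronal and axon genes, Smad3 was listed at 27 of 40 and JMJD3 at 20 (adjusted Fisher exact p = 0.2 and 0.48). Windows of 2.5 and 5 kb gave Smad3 at 30 and 31 of these 40 genes, and both were called (adjusted Fisher exact p = 0.0335 and 0.0318). The guidance genes Robo1, Nrp1, Plxna2 and Ntn1 were bound by both, and Mapt and Syt1, which act in mature neurons, by Smad3 only. Among glial genes, Smad3 was listed at 10 of 20 and JMJD3 at 7 (adjusted Fisher exact p = 0.676 and 0.555), with both at Nfib, Glul and Cnp and Smad3 only at Pdgfra. The 95% intervals for Smad3, 50.9% to 81.4% for neuronal and 27.2% to 72.8% for glial genes, included the share of all coding genes, 55.0%.

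Immediate early genes, which respond to growth factors within minutes, were bound almost without exception. Smad3 was listed at all 29 (100%, 95% CI 88.1 to 100, adjusted Fisher exact p = 1.81e-07) and JMJD3 at 28 (96.6%, adjusted p = 1.25e-08), with Fosl1 the member lacking a JMJD3 promoter peak. Dusp6, Cyr61, Jun and Egr1 had Smad3 regions of 3991, 2701, 2620 and 3171 bp and JMJD3 regions of 2870, 2520, 2480 and 2070 bp.

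Polycomb and H3K27 demethylase genes had Smad3 at 28 of 30 (93.3%, adjusted Fisher exact p = 2.04e-05) and JMJD3 at 25 (83.3%, adjusted p = 2.1e-05). Cbx8, Eed, Rbbp4 and Pcgf3, members of the Polycomb complexes, were bound by both, and Phc3 by Smad3 only. Cell cycle genes had Smad3 at 34 of 36 (94.4%, adjusted Fisher exact p = 9.23e-07) and JMJD3 at 25 (69.4%, adjusted p = 0.00308), among them E2f1, Ccne2, Cdc25a and E2f2. Rbl1 and the mitotic kinase gene Aurkb had Smad3 only. Ribosomal protein genes, transcribed in every cell, had Smad3 at 47 of 50 (94.0%, adjusted Fisher exact p = 1.28e-08) and JMJD3 at 34 (68.0%, adjusted p = 0.00088), for example Rps21, Rps19, Rplp2 and Rps18. Rpl35 and Rps14 had Smad3 only. Against genes closest to any peak, immediate early and Polycomb genes kept all calls, with adjusted Fisher exact p from 2.42e-05 to 0.00134 and from 0.014 to 0.0382. Cell cycle and ribosomal genes kept those for Smad3 (adjusted Fisher exact p = 0.000422 and 0.000847) and lost those for JMJD3 (0.167 and 0.197) and both (0.0951 and 0.167).

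Genes of other lineages were bound less often than other genes. Among transcription factors of non-neural lineages, Smad3 was listed at 8 of 40 (20.0%, adjusted Fisher exact p = 2.04e-05) and JMJD3 at 5 (adjusted p = 8.41e-05), with both at Runx1, Ebf4, Eya1 and Gata2 and Smad3 only at Tbx6 and T. Among genes of terminally differentiated non-neural cells, each factor was listed at 3 of 40 (7.5%, adjusted Fisher exact p = 8.84e-09 and 3.22e-06). Kdr and Ttr had both, Lor Smad3 only and Mb JMJD3 only. Of 39 Hox genes, Smad3 was listed at 3 and JMJD3 at 1 (adjusted Fisher exact p = 8.84e-09 and 6.75e-08). Only 9 of the 39 were named as the closest gene of any peak. Gene names alone do not show whether the others lack peaks or are missing from the annotation behind the files. By coordinates, the HoxD cluster between Mtx2 and Lnp held 3 Smad3 and 0 JMJD3 regions, so its genes lacked JMJD3 regions. The HoxA and HoxC clusters with their flanks held 25 and 10 Smad3 and 14 and 7 JMJD3 regions. Among the 9 named Hox genes, the odds ratios were 0.166 for Smad3 and 0.0863 for JMJD3 (adjusted Fisher exact p = 0.0222 and 0.014 against genes closest to any peak).

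**Figure D5:**
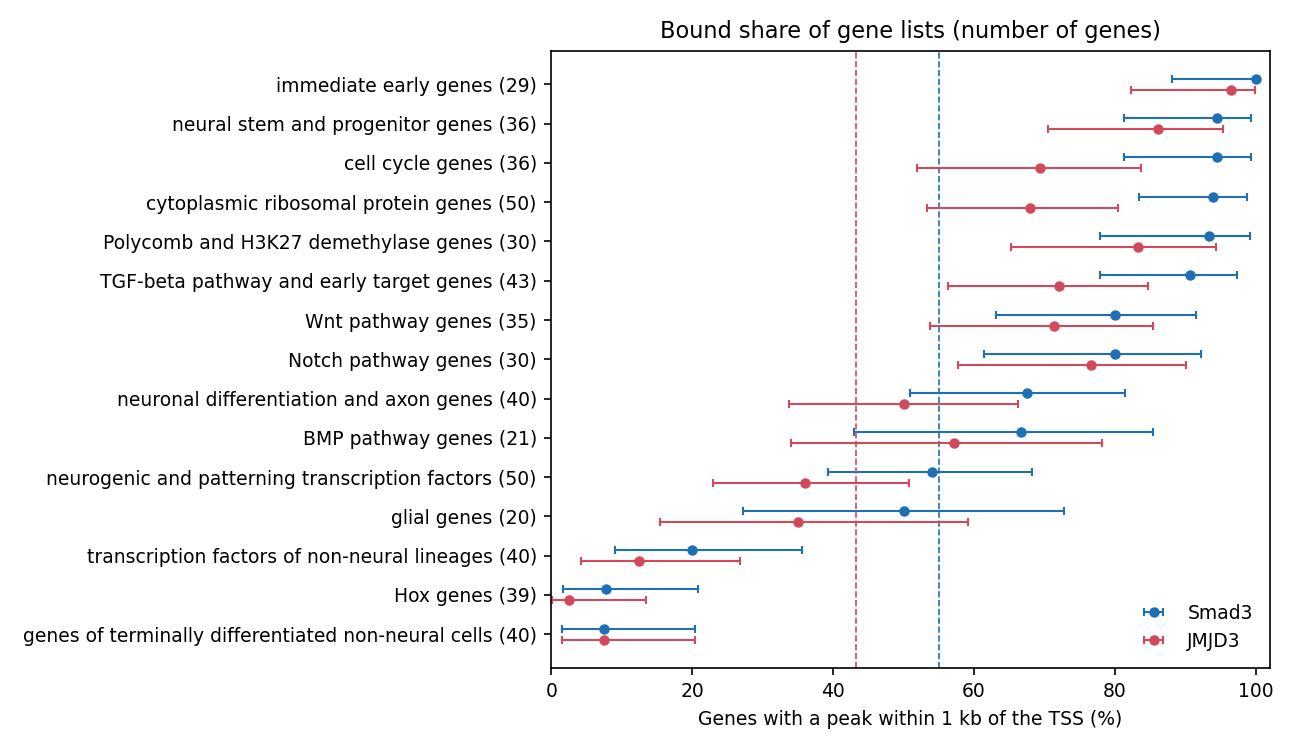
Percent of genes with a Smad3 (blue) or JMJD3 (red) peak within 1 kb of the TSS (horizontal axis) for 15 gene lists (vertical axis, number of genes in parentheses), with 95% Clopper-Pearson intervals and dashed lines at the shares of all coding genes, 55.0% for Smad3 and 43.3% for JMJD3. Immediate early genes lie highest, and Hox genes and genes of non-neural cells lowest.

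No list was called as different between the factors. Cell cycle genes had 9 members with Smad3 only and 0 with JMJD3 only, ribosomal protein genes 13 and 0, and TGF-beta genes 8 and 0 (exact McNemar p = 0.00391, 0.000244 and 0.00781). The same lean ran through all genes, 2744 against 297, and was smaller with equal numbers of peaks, 1830 against 1005. Set against the other genes bound by 1 factor, 0 of 15 lists passed by two-sided Fisher exact test, and 0 had an unadjusted p at most 0.05 (smallest 0.0779, for the Notch list). With so strong a lean in all genes, lists this small could not pass for a lean to Smad3. Even 13 against 0 gave an unadjusted Fisher exact p of 0.629. Whether such lists lean further to Smad3 than other genes is therefore not decided by this test.

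Among Smad3-bound genes, the share with JMJD3 was highest in immediate early genes, 28 of 29, and in progenitor genes, 31 of 34, against 76.1% of other Smad3-bound genes in each case. This comparison was added after the data were seen. Of 15 lists, 0 passed after adjustment and 2 had an unadjusted two-sided Fisher exact p at most 0.05, immediate early genes (p = 0.00723, adjusted p = 0.108) and progenitor genes (p = 0.0424, adjusted p = 0.318). Random Smad3-bound genes matched on region width had JMJD3 in 90.2% and 84.3% of cases, and 0 lists passed against them.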

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

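All tests in this part were chosen after the results they bear on had been seen, and the limits they were held to were set then too. Signals outside the comparisons of the report were looked at because none of its tests used them. The closest TSS was that of a non-coding RNA for 6263 Smad3 and 3973 JMJD3 peaks. At the Rn4.5s locus, a tandem array of small RNA genes on chromosome 6 from 47600611 to 47726201, 93 Smad3 peaks and 0 JMJD3 peaks were listed. Chromosome Y carried 5 Smad3 and 7 JMJD3 peaks. Whether these peaks are true signal was not tested.

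The first pattern is that 81.4% of JMJD3 peaks lay on Smad3 peaks. A shared preference for promoters is argued against, since the highest of 1000 TSS-matched placements reached 20.2%. Peaks split into neighbouring pieces are argued against as well, since 81.7% of joined JMJD3 regions overlapped Smad3 regions. Enrichment common to any antibody, or left by the input, cannot be told apart from co-occupancy, because 0 peak lists of an unrelated antibody or of the input were used here. Binding of both proteins to the same sites stays open as a hypothesis, and no untreated library was used to ask whether TGFb plays a part.

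The second pattern is that peaks lacking the other factor lay in narrower regions. Chance contact of single, evenly placed peaks is argued against. The largest difference in JMJD3 median region width over 1000 such placements was 69 bp, against observed medians of 800 bp for shared and 490 bp for other peaks. Because each peak was moved singly and evenly along its chromosome, chance contact of whole joined regions, or where peaks are dense, was not tested. Weak sites that passed in 1 list and were missed in the other remain a candidate explanation: beyond 50 kb of a TSS, the widest 10% of Smad3 regions overlapped JMJD3 in 95.8% of cases (95% CI 94.9 to 96.6) and the narrowest 10% in 30.9%. The same gradient would arise from sites where both proteins bind more strongly, and no biological explanation was tested.

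The third pattern is that Smad3 regions at immediate early genes were wide, with a median of 1510 bp against 760 bp for random lists of bound genes (adjusted permutation p = 0.00173 from 10000 random lists, 26 tests, 27 of 29 above the median of all bound genes). Regions shared by neighbouring genes are argued against, since with regions closest to 1 gene only the median was 1420.5 bp. Ribosomal protein genes stood in for strongly transcribed genes, and the median of 1510 bp exceeded theirs by 650.0 bp (two-sided permutation p = 1e-05, the smallest possible). This argues against equally wide regions at ribosomal protein genes only. Other strongly transcribed genes were not compared, so strong transcription in general stays open. Transcription of these genes was not measured here, so open chromatin at genes induced by medium or TGFb stays untested.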

How the results depend on the processing

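Joined regions, peaks beyond 50 kb of a TSS, peaks credited to every listed TSS, the background of genes closest to a peak, and each setting of the JMJD3 comparison within Smad3-bound genes were chosen after seeing the data. The overlap of the lists kept its direction and its call under every placement, overlap rule and peak subset run, with 31.4% to 81.7% of JMJD3 and 37.4% to 60.8% of Smad3 peaks overlapping. So did the promoter odds ratios (2.07 to 7.17 for JMJD3, 1.27 to 2.06 for Smad3), the width difference (19.3 to 39.3 and 18.7 to 36.6 percentile points) and the gene-level odds ratio (33.3 to 203). No peak was wider than 5 kb, so that alternative removed chromosome Y only. The share of peaks at promoters changed by construction with the window: at 5 kb it was 36.5% for Smad3 and 33.9% for JMJD3. It was 36.6% and 35.4% in the wider 50% of peaks and 21.5% and 22.2% of joined regions, and the cause was not tested. The gene lists depended on the background. Against genes with a peak of either factor, 0 of 45 tests were called more often and 0 less often, in place of 24 and 9, with only bound genes left to compare by construction. Odds ratios then fell below 1 for Notch genes with Smad3 (0.308), Wnt genes with Smad3 (0.721), cell cycle genes with JMJD3 (0.839) and both (0.962), and ribosomal protein genes with JMJD3 (0.79) and both (0.905), each without a call. Against genes closest to a peak at any distance, 12 tests were called more often and 11 less often. The other settings gave 24 or 25 and 9. The additional call, with windows of 2.5 and 5 kb, was that of neuronal genes with Smad3. Of the values for single genes, lists and classes under an alternative, 834 kept their direction and side of the threshold, 74 moved, 39 lost a call, 4 gained one and 6 reversed, as given above. For list odds ratios not called in the main setting, moved means that the direction changed. Among lists, reversed was kept for odds ratios called in the main setting, so the 6 are not all changes of direction. The difference between factors was called for 0 lists under each setting run. With equal numbers of peaks, ribosomal protein genes had 13 members with Smad3 only and 1 with JMJD3 only. Their unadjusted two-sided Fisher exact p was 0.0253 (adjusted p = 0.38). In the JMJD3 comparison within Smad3-bound genes, 1 list was called with the 5 kb window, Hox genes, where 1 of 7 had JMJD3 (adjusted Fisher exact p = 0.0132, against 0.346 to 0.358 with 1 kb). Against Smad3-bound genes of like region width at 5 kb, of which 50.4% had JMJD3, it was not called (adjusted permutation p = 0.752), and the cause stays open. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. The search for sequence elements was not run. Read depth is unknown, so a gene without a listed peak is not shown to be unbound.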

Other observations

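All tests in this part were chosen after the data had been seen. Immediate early, TGF-beta and stem cell genes also had many distal Smad3 regions. These lay more than 1 kb from every listed TSS and within 50 kb of the gene's own TSS. Each was counted for every gene in reach, so neighbouring genes can share regions. The median was 9 for immediate early genes, 8 for TGF-beta genes, 7 for progenitor genes, 6.5 for glial genes and 6 for Notch genes, against 3 for random lists (adjusted permutation p = 0.0012, 0.0012, 0.0012, 0.0262 and 0.018, 10000 random lists, 30 tests). For JMJD3 the lists called were immediate early genes (median 5 against 2), progenitor genes (4 against 2) and glial genes (4 against 1.5), with adjusted permutation p = 0.0012, 0.0012 and 0.018. TGF-beta genes were not called for JMJD3 (3 against 2, adjusted permutation p = 0.0687). The glial genes passed here although their promoters were not bound more often than other genes. Single genes with many distal Smad3 regions were Cxxc5 (33), Itpkb (32), Mtss1l (32), Creb3l2 (30) and Slc38a3, Nfix and Map4k4 (29 each). Olig1, Notch1 and Pmepa1, a TGF-beta target, had 28. For 3 lists (Hox genes and both lists of non-neural genes) fewer than 80% of members had a value, so that check is void for them.

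Smad3 promoter regions were also wider at progenitor genes (median 1050.5 bp, adjusted p = 0.0026), TGF-beta genes (1030 bp, adjusted p = 0.00312) and cell cycle genes (965.5 bp, adjusted p = 0.0407) than the 760 bp of random lists (permutation tests, 26 in the set). With regions closest to 1 gene only, the cell cycle genes lost the call (860 bp, adjusted permutation p = 0.192). JMJD3 regions were wide at TGF-beta genes (1180 bp) and immediate early genes (1175.5 bp), against 860 bp for random lists (adjusted permutation p = 0.00173 each).

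A screen of 226 symbol prefixes led to 10 gene families that were picked for their values, and their p-values were adjusted over all 708 tests of screen and families. Of the 678 tests of the screen, 135 were called more often bound and 143 less often, so a call was common among prefixes. Lysine demethylase genes (Kdm) had Smad3 at 17 of 17 and JMJD3 at 15 (adjusted Fisher exact p = 0.000329 and 0.000973), and proteasome subunit genes (Psm) at 46 and 40 of 51 (adjusted p = 1.06e-06 and 4.9e-06). Mitochondrial ribosomal protein genes had Smad3 at 70 and JMJD3 at 50 of 78 (adjusted Fisher exact p = 9.17e-10 and 0.0013). Olfactory receptor genes had Smad3 at 3 and JMJD3 at 2 of 1108, and vomeronasal receptor genes at 3 and 0 of 355. Defensin genes (70) and keratin-associated protein genes (56) had 0 listed for either factor.

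Fewer genes of chromosome X were listed as bound. Smad3 was listed at 324 of 905 X-linked coding genes (35.8%) against 55.9% of autosomal ones, and JMJD3 at 243 (26.9%) against 44.1% (two-sided Fisher exact p = 2.05e-32 and 1.43e-25). No autosome was lower, with ranges of 42.8% to 65.7% and 33.9% to 53.0%. The comparison was not repeated against genes closest to any peak. Read depth on chromosome X is unknown, and the background may hold genes that the files' annotation lacks, so the cause was not tested. Genes with JMJD3 and no Smad3 promoter peak had narrower JMJD3 regions (median 610 bp against 860 bp at genes with both, not tested), the widest at Akt1s1 with 2440 bp. The widest Smad3 region at a gene without a JMJD3 promoter peak lay at Tcfap4, with 3150 bp, followed by Phldb1 with 2271 bp.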
